A study of Mus musculus with 2 samples.

How the data were processed

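Liver RNA of male C57Bl/6J mice was measured on Affymetrix GeneChip expression arrays. Per the labels' protocols, mice aged 9 weeks at the start received a diet depleted in n-3 polyunsaturated fatty acids for 112 days, with sunflower oil in place of soybean oil. In the last 10 days, 1 group stayed on that diet and drank fructooligosaccharides (FOS), a fermentable fibre, at an intake of 0.25 g per day (DEF/FOS). The other group was returned to the soybean oil control diet (DEF/CT). The ratio of n-6 to n-3 fatty acids was 127.2 in the depleted diet and 6.9 in the control diet. Equal amounts of RNA from the mice of each group were pooled, per the labels' protocols, and each pool was put on 1 array. The treatment protocol gives 8 mice for each of these groups, and the extract protocol gives a range of 4 to 8 mice per group. The groups kept on the depleted diet alone and on the control diet throughout are not analysed here.

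The deposited values are MAS5 signal intensities on a linear scale, 1 for each of 45101 probe sets and each array, and the tools GCOS and MAS5 are named in the submitters' processing notes without a version. The trimmed mean of the deposited signals, with 2% left out at each end, was 100.00 in both arrays, so the authors' values are scaled to a common mean. The table holds no detection calls and no background values. With 1 array per group, the spread between arrays cannot be measured. Of the probe sets, 64 are array controls.

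Gene symbols came from the platform's annotation, which can be old. It listed 35890 probe sets, of which 34958 had 1 gene symbol and 932 had several, and 9160 further probe sets that are not controls were not listed and stay unnamed here. Symbols were updated through Entrez identifiers in a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. The identifier matched for 34754 probe sets and 0 symbols had to be updated. No probe set with several symbols was named or counted as a gene.

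The log2 signal of the DEF/CT pool was subtracted from that of the DEF/FOS pool, with no offset. The differences were centred on their median over the probe sets above a signal floor, which was -0.01 before centring. The floor was a mean log2 signal of both arrays at or above the median of all probe sets that are not controls, a signal of 19.4. This floor was chosen here and is not a detection call. Each gene was represented by its probe set of highest mean signal, and 11163 genes lay above the floor. Where 1 pool lay below the floor, the fold was computed against the floor and is printed as a lower bound. Folds come from the centred differences, so they can differ slightly from the ratio of the printed signals.

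With 1 array per group there is no replicate, no test and no p-value. Genes were counted at a difference of at least 2-fold. For each of 45 gene lists, the median difference of the members above the floor was placed among 10000 random lists of the same size matched on mean signal in 20 bins. That percentile describes these 2 arrays and does not measure the spread between animals. Members were also counted at 1.5-fold. A list with fewer than 4 members above the floor received no percentile. Of the 950 entries of the lists, 123 had no probe set named for the gene alone.

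The design, the lists, the naming rule and most alternatives were fixed before the data were examined. The rule named the 12 genes with the largest positive and the 12 with the largest negative difference at 2-fold or more, provided that all their probe sets above the floor had the same sign and that the symbol was no clone or model name. It also named up to 4 members of each list with the largest absolute difference, and 16 genes by symbol, of which 4 had no probe set named for them alone. Genes named outside the rule are said to be so where they appear. Further lists of skeletal and smooth muscle genes, and the repeats of the first part of the rule above the 75th percentile of signal without muscle genes and again with signals below the floor set to the floor, were added after the data had been seen.

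The SD between probe sets of the same gene above the floor was used as the technical spread. It was 0.38 on the log2 scale over 4885 genes with more than 1 such probe set, and it was 0.57 at signals of 19.4 to 37.4 and 0.23 at signals above 235. It leaves out the spread between animals and between arrays.

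The procedure was tested on simulated data of 11226 genes in which known fold changes were put in, with noise drawn from the spread across genes of these arrays. That spread includes true differences, so the simulated noise may be too large. The share found at least 2-fold apart in the right direction was 12.2% of genes changed 1.5-fold, 31.9% of genes changed 2-fold, 93.8% of genes changed 3-fold and 100.0% of genes changed 5-fold. In the same simulation 353 unchanged genes, 3.2% of them, came out at least 2-fold apart, and 7 did so above the 75th percentile of signal. Of 100 simulated lists of 20 unchanged genes, 7 fell outside the central 95% of random lists, and all 100 lists raised by 0.5 on the log2 scale lay above it.

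Counts were recomputed under 14 settings and list medians under 11, the main setting included in both. The alternatives were no centring, a loess correction with a span of 0.3, quantile normalization, an offset of 32, the median over probe sets, the removal of probe sets that may match several transcripts, no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, and a requirement that all probe sets pass. The removal of muscle genes and the setting of low signals to the floor, 2 in number, were added after the data had been seen. Percentiles in the alternatives rest on 2000 random lists each. Which list medians count as main results was settled after the list values had been seen: the lists on lipid metabolism, and those outside the central 95% of random lists. Other floors looked at while exploring the data are not reported. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9.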

Results

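Liver gene expression was compared between 2 groups of mice that had been depleted of n-3 polyunsaturated fatty acids and were treated differently in the last 10 days. The DEF/FOS pool came from mice kept on the depleted diet with fructooligosaccharides in the drinking water, and the DEF/CT pool from mice returned to the control diet. The treatment protocol gives 8 mice for each of these groups. The study's title places the comparison in the question of how the gut microbiota bears on fat accumulation in the liver under n-3 depletion. The pools differed both in the fibre and in the oil of the diet, so no difference below can be assigned to either. Each pool was measured on 1 array, and no difference below has a replicate check.

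The median signal was 19.6 in the DEF/FOS pool and 21.9 in the DEF/CT pool, and Pearson's r of the log2 signals across probe sets above the floor was 0.967, where probe sets are not independent replicates. Albumin (Alb), the main plasma protein made by hepatocytes, had signals of 11023 and 11303 in the DEF/FOS and DEF/CT pools. The signal ratio of the 3-prime to the 5-prime probe sets of the actin control was 1.97 in the DEF/FOS pool and 2.16 in the DEF/CT pool. For the Gapdh control it was 0.720 and 0.737. For the pyruvate carboxylase control it was 5.88 and 6.73. The hybridisation spikes had a median log2 difference of -0.07 with an SD of 0.06 over 18 probe sets. The polyA spikes had one of -0.17 with an SD of 0.21 over 24 probe sets, and ran from -0.67 to 0.27.

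The metallothioneins Mt2 and Mt1, metal-binding stress proteins, and the fatty acid omega-hydroxylase Cyp4a14 were among the genes with the largest positive differences. Mt2 had a signal of 1706 in the DEF/FOS pool and 65.6 in the DEF/CT pool, a 26.3-fold difference. Mt1 was 15.9-fold higher in the DEF/FOS pool, a log2 difference of 3.99 against 2.72 for its other probe set, and Cyp4a14 was 14.0-fold higher, at 6061 against 438. Also higher in the DEF/FOS pool were the glutathione transferases Gstm3, by 5.02-fold, and Gsta2, by 5.00-fold. The receptor Tnfrsf12a was 5.74-fold higher and the iron-carrier-binding protein Lcn2 5.79-fold. The chemokine Cxcl1 was 5.23-fold higher by its brightest probe set, with log2 differences from 0.50 to 2.39 over its 3 probe sets. Zfp9, Rad51b, Cdk1 and Sema3f lay below the floor in the DEF/CT pool and were at least 5.89-fold, 10.8-fold, 3.99-fold and 3.83-fold higher in the DEF/FOS pool. With signals below the floor set to the floor, a ranking added after the data had been seen, 10 of the 12 higher genes stayed, and S100a8 and Dmbt1, the latter named after its values were seen, took the place of Cdk1 and Sema3f.

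Of the 12 genes that the naming rule took for the largest negative differences, 11 encode proteins of skeletal muscle, and the other was Slc22a7, an organic anion transporter of the liver, 7.49-fold lower in the DEF/FOS pool at 73.2 against 555. The muscle genes were Tnnc2, Myl1, Myh1, Acta1, Tnnt3, Myh4, Ckm, Pvalb, Neb, Atp2a1 and Mybpc1. In 9 of the 12 genes the DEF/FOS signal lay below the floor, where signals have no order. In the ranking with such signals set to the floor, 10 of the 12 stayed, and Tnni2 and Mylpf, muscle genes named after their values were seen, took the place of Pvalb and Mybpc1. When the ranking was repeated above the 75th percentile of signal without muscle genes, a repeat chosen after the data had been seen, the lower genes after Slc22a7 were led by Hsd3b5, Mup10 and Upp2. Hsd3b5, a steroid dehydrogenase of male mouse liver, was 4.23-fold lower in the DEF/FOS pool at 796 against 3404. Mup10, a major urinary protein gene, was 3.74-fold lower and the uridine phosphorylase Upp2 3.52-fold. Next came Ighm, 3.29-fold lower with probe sets that disagreed in sign, and Slc25a4, 2.98-fold lower at 77.5 against 233. The coagulation factor gene F11 followed, 2.90-fold lower. The removal in this ranking covered only the muscle genes of the lists, so further genes expressed in muscle may remain. The same ranking added Acnat2, Cdkn1a, Ccnd1, Acot3 and Acot1 to the higher genes.

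In all, 194 genes were at least 2-fold higher and 245 at least 2-fold lower in the DEF/FOS pool among 11163 genes above the floor, so that 44.2% of these differences were positive. Quantile normalization gave 227 higher and 192 lower, or 54.2% positive. In arrays simulated with the spread of these arrays, 353 unchanged genes passed 2-fold at this floor, where the observed total was 439. That noise was set from the observed spread across genes, true differences included. A simulated count near the observed one was therefore largely built in and cannot show how many of the 439 are noise. Of the 439, 207 had 1 pool below the floor. Above the 75th percentile of signal, 59 genes were higher and 28 lower among 6751. In the simulation 7 unchanged genes passed 2-fold above the 75th percentile of the simulated signals, which is a different set of genes with the same limit on the noise. Without the listed muscle genes the counts at the main floor were 194 and 223.

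**Figure D1:**
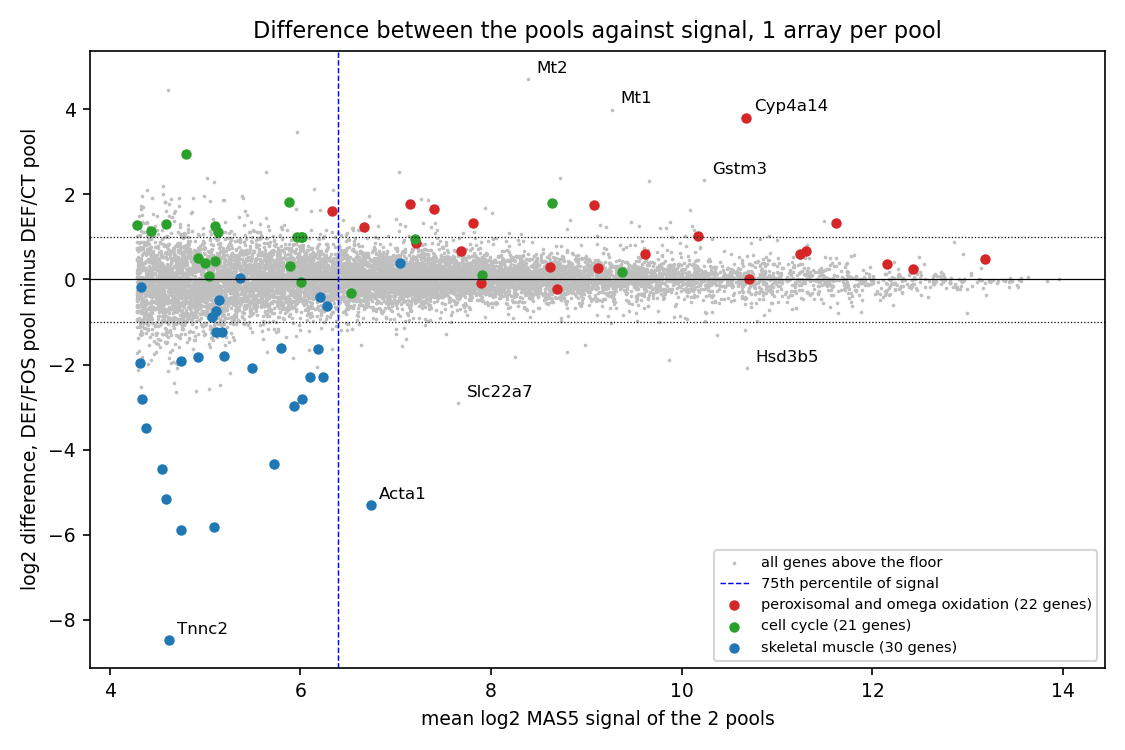
Each grey point is 1 gene above the floor, with the mean log2 MAS5 signal of the pools on the x axis and the log2 difference, DEF/FOS minus DEF/CT, on the y axis; coloured points mark 22 peroxisomal and omega oxidation genes, 21 cell cycle genes and 30 skeletal muscle genes. Mt2, Mt1 and Cyp4a14 stand at 4.72, 3.99 and 3.80, most cell cycle and muscle genes lie left of the 75th percentile of signal (dashed line), and dotted lines mark 2-fold.

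Genes of peroxisomal and omega oxidation of fatty acids were higher in the DEF/FOS pool as a group. Of 22 members above the floor, 14 were at least 1.5-fold higher and 0 at least 1.5-fold lower. After Cyp4a14 the largest differences were those of the acyl-CoA thioesterases, with Acot3 3.41-fold, Acot1 3.34-fold and Acot2 3.17-fold higher, although the probe sets of Acot2 disagreed in sign. Ehhadh, the peroxisomal bifunctional enzyme, was 2.51-fold higher at 4955 against 1992, a value given outside the naming rule. The list's median difference was 0.67 on the log2 scale, at percentile 100 of random lists, and it lay between 0.58 and 0.72 over the 11 settings.

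Mitochondrial oxidation enzymes were also higher in the DEF/FOS pool, by smaller amounts. All 18 members had positive differences, with a median of 0.38 at percentile 100 of random lists, and 1 of them was at least 1.5-fold higher. That member was Eci2, an enoyl-CoA isomerase, 1.93-fold higher, which was also entered in the peroxisomal list under its older name Peci. With any 1 member left out, the median of the mitochondrial list was at least 0.36. The carnitine palmitoyltransferase Cpt2 was 1.45-fold higher, the carnitine carrier Slc25a20 1.45-fold and the dienoyl-CoA reductase Decr1 1.44-fold. Cpt1a, the entry step of mitochondrial fatty acid oxidation, differed by 0.18 on the log2 scale. Ketone body synthesis had 4 members above the floor, with a median of 0.40 at percentile 99.0, or 0.31 at percentile 97.45 with the median over probe sets, of which the transporter Slc16a1 was 1.62-fold and Bdh1 1.54-fold higher.

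Other target genes of PPARα, the fatty-acid-activated receptor of the liver, went both ways. Retsat was 2.47-fold and Vnn1 2.40-fold higher in the DEF/FOS pool, Cidec, a lipid droplet protein, at least 2.33-fold higher, and Pdk4 1.52-fold higher. Fabp3, which is also a muscle gene, was 4.22-fold lower. The receptor's own gene, Ppara, had signals of 963 and 1300 in the DEF/FOS and DEF/CT pools. Over 18 members, 6 were at least 1.5-fold higher and 3 lower, with a median of 0.09 at percentile 91.2. Without muscle genes the median was 0.16 at percentile 98.4.

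Among lipid droplet and lipolysis genes, Cidec and the monoglyceride lipase Mgll, 1.49-fold higher, stood against G0s2, an inhibitor of lipolysis, 1.65-fold lower in the DEF/FOS pool. The median of 16 members was 0.20 at percentile 99.5.

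Cholesterol synthesis genes were slightly higher in the DEF/FOS pool, with 11 of 17 members above 0. Sqle, which makes squalene epoxide, differed by 0.59 on the log2 scale and Hsd17b7 by 0.51. The median was 0.19 at percentile 99.2, but it was 0.04 at percentile 70.4 when the median over each gene's probe sets was taken. Sterol-regulated uptake and control genes had a median of -0.20 at percentile 1.06 over 9 members, but one of -0.13 at percentile 5.65 with the median over probe sets. Within this list Srebf2, the regulator of cholesterol synthesis, was 1.70-fold higher and Rdh11 1.43-fold lower. Scap, the escort protein of the same pathway, was 1.44-fold lower, with probe sets that disagreed in sign.

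Fatty acid and triglyceride synthesis genes did not stand apart from random lists. Their median was -0.05 at percentile 14.9 over 23 members, with 1 at least 1.5-fold higher and 2 lower, and its sign was not the same in all settings. The liver pyruvate kinase Pklr was 1.80-fold and the lipase-like Pnpla5 1.79-fold lower in the DEF/FOS pool, and Mid1ip1, an activator of acetyl-CoA carboxylase, 1.66-fold higher. Fatty acid synthase (Fasn) differed by 0.25, the lipogenic regulator Srebf1 by 0.14 and the desaturase Scd1 by -0.01 on the log2 scale, the last with probe sets that disagreed in sign. The oxysterol receptor gene Nr1h3 differed by -0.38. Polyunsaturated fatty acid synthesis had a median of 0.03 at percentile 74.9 over 9 members, with Fads2, the first desaturase of this pathway, 1.29-fold higher. Fads1 was 1.24-fold higher with disagreeing probe sets. Lipoprotein genes had a median of -0.01 at percentile 54.0 over 22 members, of which Pltp was 1.71-fold and Apoa4 1.51-fold higher.

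Bile acid synthesis and transport genes were lower in the DEF/FOS pool as a group, with a median of -0.15 at percentile 0.16 over 23 members. The sterol 12-alpha-hydroxylase Cyp8b1 was 1.88-fold lower, the uptake transporter Slco1a1 1.79-fold and the oxysterol hydroxylase Cyp7b1 1.72-fold. The export pump Abcc3 was 1.60-fold higher and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 1.49-fold higher.

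Amino acid catabolism and urea cycle genes were lower in the DEF/FOS pool in 31 of 35 members, with a median of -0.25, below all 10000 random lists. Bhmt, which remethylates homocysteine, had a difference of -0.79. The aspartate aminotransferase Got1 differed by -0.77, the kynureninase Kynu by -0.62 and Agxt by -0.56. Genes known to be higher in male than in female mouse liver had a median of -0.52 over 15 members, also below all 10000 random lists, with 7 at least 1.5-fold lower and 0 higher. Slco1a1 and Cyp7b1 both belong to the bile acid list too. Besides these genes and Hsd3b5, the glucuronosyltransferase Ugt2b38 was 2.11-fold lower. Female-biased genes had a median of 0.26 at percentile 95.1 over 7 members, and one of 0.72 at percentile 99.9 over the 4 members above the 75th percentile of signal. With an offset of 32 the percentile was 98.25. With the median over probe sets, however, the median of the female-biased list was 0.15 at percentile 86.65. Without probe sets that may match several transcripts it was 0.20 at percentile 90.10. This list lay outside the central 95% of random lists in 2 of the 11 settings. The largest differences were those of Acot3 and Abcd2, which are also in the peroxisomal list.

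Detoxification genes were higher in the DEF/FOS pool on balance. In xenobiotic metabolism, 7 of 29 members were at least 1.5-fold higher and 2 lower, with a median of 0.23 at percentile 100. Gsta4 was 2.33-fold higher beside Gstm3 and Gsta2, and the cytochrome P450 gene Cyp2c54 2.47-fold lower. Targets of NRF2, a regulator of the oxidative stress response, had a median of 0.38 at percentile 99.99 over 15 members. Ephx1, an epoxide hydrolase, was 2.57-fold higher at 4583 against 1800, the carbonyl reductase Cbr3 at least 2.32-fold and the thioredoxin reductase Txnrd1 1.68-fold. Srxn1 was 2.13-fold higher, with probe sets that disagreed in sign.

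Genes of the glucocorticoid and stress list and heat shock genes were higher in the DEF/FOS pool. The first list joins glucocorticoid and general stress genes, so its median does not measure a glucocorticoid response alone. In the glucocorticoid and stress list, 7 of 21 members were at least 1.5-fold higher and 0 lower, with a median of 0.30 at percentile 99.97, but of 0.13 at percentile 94.8 above the 75th percentile of signal. After the metallothioneins and Lcn2 the largest difference was that of Ier3, 3.91-fold higher at 82.1 against 21.2, the latter close to the floor. Cdkn1a, a cell cycle inhibitor, was 3.68-fold higher, with log2 differences of 1.17 and 1.88 in its 2 probe sets. Heat shock genes had a median of 0.38 at percentile 100 over 17 members, 16 of them above 0. Hspa1b was 2.54-fold, Hspb1 2.05-fold and Chordc1 1.75-fold higher, and Cryab, which is also a muscle gene, 3.11-fold lower.

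Cell cycle genes were higher in the DEF/FOS pool, mostly at low signal. Of 21 members above the floor, 12 were at least 1.5-fold higher and 0 lower, with a median of 0.99 at percentile 100, or 0.73 with signals below the floor set to the floor. Ccnd1, the G1 cyclin, was 3.46-fold higher at 739 against 216, with log2 differences from 1.09 to 1.79 over its 3 probe sets. The mitotic activator Cdc20 was 3.55-fold higher at 110 against 31.3, and the mitotic kinase gene Cdk1 at least 3.99-fold higher. Ube2c was at least 1.96-fold higher. The median signal of the members was 65.9 in the DEF/FOS pool and 32.3 in the DEF/CT pool. Above the 75th percentile of signal 5 members were left, and their median was 0.14 at percentile 82.9.

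**Figure D2:**
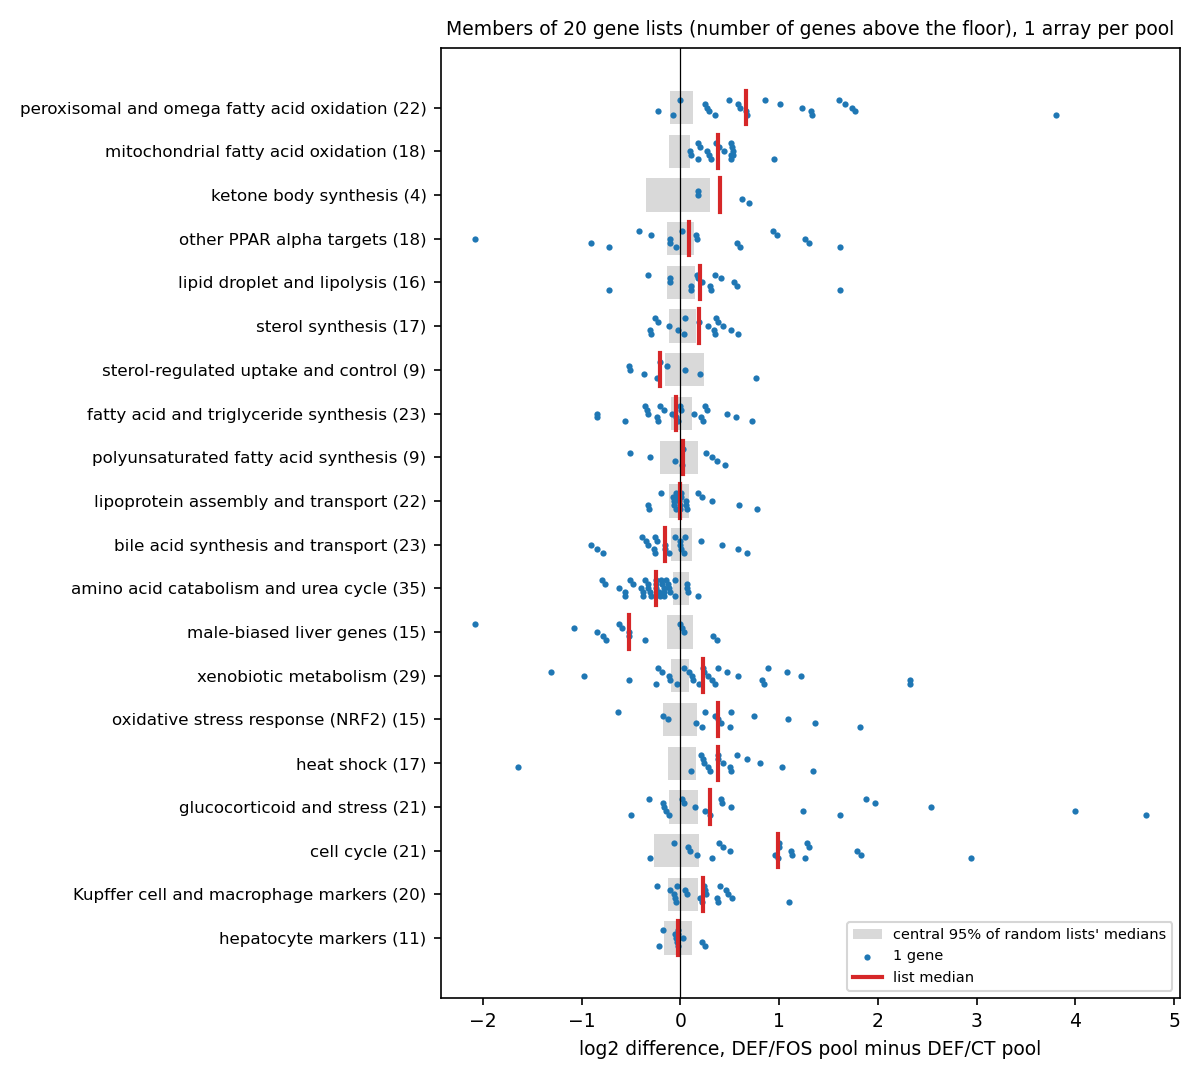
Blue points are genes of 20 lists on the log2 difference, DEF/FOS minus DEF/CT, red bars are list medians and grey bands hold the central 95% of the medians of random lists matched on signal. The red bars of peroxisomal and mitochondrial oxidation, at 0.67 and 0.38, and of amino acid catabolism and male-biased genes, at -0.25 and -0.52, lie outside their bands, and that of hepatocyte markers, at -0.03, lies inside.

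Markers of skeletal muscle were far lower in the DEF/FOS pool. Acta1, skeletal muscle actin, had a signal of 16.9 against 677 in the DEF/CT pool and was at least 34.5-fold lower, and the troponin gene Tnnc2 was at least 23.7-fold lower. The myosin gene Myl1 was at least 10.6-fold lower, Tnnt3 at least 7.38-fold and Myh4 at least 5.59-fold. The list of muscle and gallbladder wall markers had a median of -4.40 over 8 members, below all random lists, and one of -2.68 with signals below the floor set to the floor. With further muscle genes added after the data had been seen, 22 of 32 muscle genes above the floor were at least 2-fold lower in the DEF/FOS pool and 0 at least 2-fold higher.

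**Figure D3:**
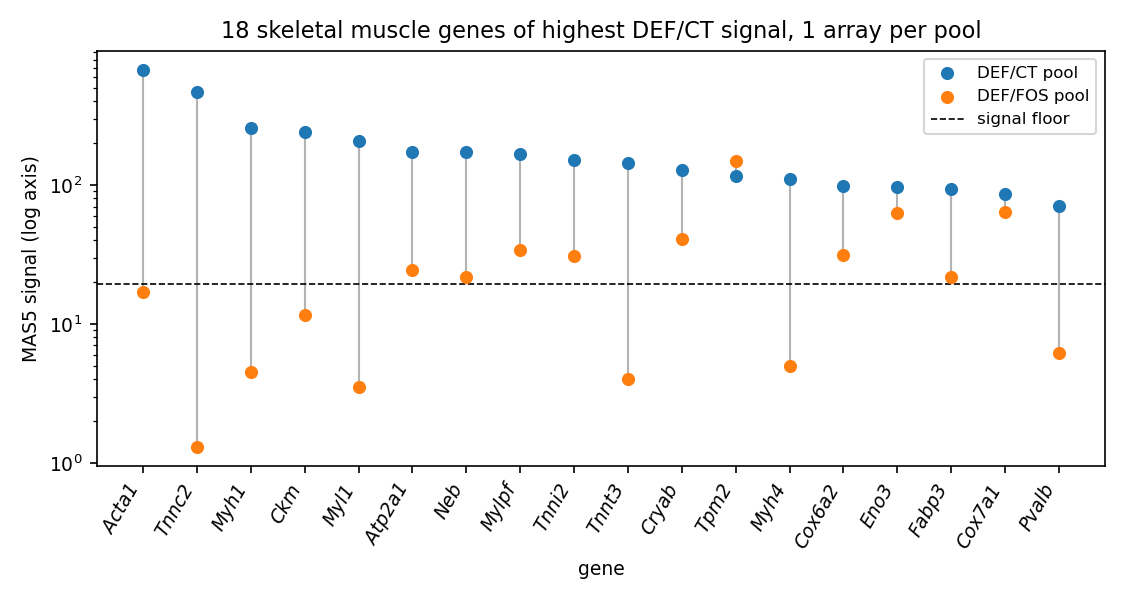
Signals of the 18 skeletal muscle genes with the highest DEF/CT signal are shown for both pools on a log axis, with 1 array per pool and the signal floor of 19.4 as a dashed line. In 8 of the 18 genes the DEF/FOS signal lies below the floor, and Tpm2 alone is higher in the DEF/FOS pool, at 150 against 115, a gene named after its values were seen and with probe sets that disagree in sign.

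Hepatocyte markers differed little, with a median of -0.03 at percentile 43.0 over 11 members and Hnf4a 1.19-fold higher as the largest. Neutrophil markers had a median of 1.06 at percentile 100 over 6 members, but 0.20 at percentile 86.9 with no floor. With 1 member left out, the median ran from 0.46 to 1.66. The largest member was Lcn2, which is also in the acute phase and the glucocorticoid and stress lists. S100a8 was 4.38-fold and S100a9 3.16-fold higher in the DEF/FOS pool. Kupffer cell and macrophage markers had a median of 0.23 at percentile 99.6 over 20 members, led by the scavenger receptor Marco, 2.14-fold higher. B and plasma cell markers had a median of -0.46 at percentile 3.91 over 7 members, or -0.51 at percentile 1.5 over 9 with no floor, led by Ighm, 3.29-fold lower with disagreeing probe sets. T and NK cell markers had a median of 0.22 at percentile 86.9 over 5 members. Exocrine pancreas markers had a median of -0.33 at percentile 0.18 over 12 members, with Cela1, an elastase, 2.03-fold lower.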

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

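Low signal and the single array per group limited the results. No list median that lay outside the central 95% of random lists in the main setting changed sign in any setting. Of the recomputed list medians 402 moved by less than the SD of random lists and 44 by more, and of the recomputed named genes 1335 differences moved by less than the probe set SD and 73 by more. Part of these comparisons could not move. The median removed by centring, -0.01, is smaller in size than any of these SDs. Removing muscle genes changes a list median only where the list holds such genes, and the floor acts only on signals below it. The counts are therefore no measure of robustness. The removal of muscle genes and the setting of low signals to the floor were chosen after seeing the data. No paired analysis was possible because each group had 1 array. For the values below, the cause was not tested, except where a floor or threshold by its construction changes the genes counted.

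Genes at least 2-fold apart, 439 in the main setting with 194 higher and 245 lower, numbered 95 with an offset of 32 (55 higher, 40 lower), 3983 with no floor (1661 and 2322) and 87 with the floor at the 75th percentile (59 and 28). They numbered 1627 at 1.5-fold (754 and 873), 110 at 3-fold (52 and 58) and 25 where all of at least 2 probe sets had to pass (18 and 7). No centring gave 189 and 257, the loess correction 213 and 194, quantile normalization 227 and 192, the median over probe sets 175 and 228, the removal of probe sets that may match several transcripts 178 and 238, the removal of muscle genes 194 and 223, and low signals set to the floor 157 and 178. The percent higher, 44.2 in the main setting, was 54.2 with quantile normalization, 57.9 with the offset, 67.8 with the stricter floor and 72.0 where all probe sets had to pass.

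With an offset of 32 the list medians moved to 0.25 for NRF2 targets, 0.20 for glucocorticoid and stress, 0.49 for cell cycle, 0.65 for neutrophil markers and -2.11 for muscle and gallbladder wall. With the median over probe sets they moved to 0.043 for sterol synthesis, 0.58 for peroxisomal oxidation, -0.29 for amino acid catabolism and 0.81 for cell cycle. Without probe sets that may match several transcripts they moved to 0.11 for sterol synthesis (percentile 91.7), 0.16 for other PPARα targets, -0.60 for male-biased genes and 0.46 for neutrophil markers (percentile 96.2). With no floor they moved to 0.010 for fatty acid synthesis, 0.43 for mitochondrial oxidation, 0.31 for lipid droplets, 0.049 for lipoproteins, -0.10 for bile acids, -0.19 for amino acid catabolism, 0.20 for neutrophil markers and -3.26 for muscle and gallbladder wall. With the floor at the 75th percentile they moved to 0.093 for sterol synthesis (percentile 93.0), 0.12 for polyunsaturated fatty acid synthesis, 0.60 for ketone body synthesis with 3 members left, 0.17 for xenobiotic metabolism, 0.13 for glucocorticoid and stress, 0.14 for cell cycle, and -0.50 for exocrine pancreas, while muscle and gallbladder wall had 1 member left, at -5.34. Without muscle genes other PPARα targets moved to 0.16, and with low signals set to the floor cell cycle moved to 0.73 and muscle and gallbladder wall to -2.68.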

Other observations

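Several further gene lists lay near or beyond the edge of random lists. Glycolysis and glycogen genes had a median of -0.15 at percentile 1.41 over 15 members, but lay at percentile 3.25 after the loess correction and 6.75 after quantile normalization, with Pgm2 1.88-fold lower in the DEF/FOS pool and the fructose kinase Khk 1.38-fold lower. Periportal hepatocyte markers had a median of -0.16 at percentile 1.29 over 13 members and pericentral markers one of -0.21 at percentile 1.44 over 15, the latter at percentile 4.05 after the loess correction. Endoplasmic reticulum stress genes had a median of -0.09 at percentile 4.85 over 25 members, with Pdia4, a protein disulfide isomerase, 2.06-fold lower. Stellate cell markers had a median of -0.17 at percentile 4.29 over 14 members, with Vipr1 2.33-fold lower in the DEF/FOS pool at 23.0 against 54.2. The percentile of this list was 1.10 without muscle genes and 1.85 with no floor, but 22.15 with the median over probe sets. It was 20.45 without probe sets that may match several transcripts. Proteasome genes had a median of 0.09 at percentile 94.5 over 31 members.

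The clock output gene Dbp was 2.42-fold lower in the DEF/FOS pool, Nr1d1 1.55-fold lower and Cry1 1.57-fold higher, while the circadian list of 18 members had a median of -0.06 at percentile 22.6. With the floor at the 75th percentile its median was -0.20 at percentile 1.80 over 11 members, and with the median over probe sets 0.02 at percentile 58.55. The acute phase list had a median of 0.00 at percentile 54.3 over 23 members, within which Lcn2 and Steap4, 2.04-fold higher in the DEF/FOS pool, stood apart. Medians were -0.05 for 30 interferon response genes, -0.06 for 6 genes of MHC class II presentation, 0.01 for 48 genes of oxidative phosphorylation, -0.01 for 32 ribosomal protein genes, 0.03 for 13 selenium and one-carbon genes and -0.11 for 16 matrix genes, all inside the central 95% of random lists. Sinusoidal endothelial markers had a median of -0.08 over 18 members, cholangiocyte markers 0.35 over 4 and adipocyte markers 0.14 over 4, also inside. Of the red blood cell list 2 members lay above the floor, and Alas2 was 1.88-fold lower.

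In what follows, the tests of smooth muscle, of less liver RNA, of a fasted state and of immune cells, and the value for dim cell cycle genes, were chosen only after the result was seen. The bound of the fasted-state test was also changed after its value was known: the first bound took all fasting genes to move by about as much as the peroxisomal genes, and by it the value had counted against a fasted state.

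Skeletal muscle genes were far lower in the DEF/FOS pool, with Acta1 at 16.9 against 677. Smooth muscle of the gallbladder or vessel wall was tested with 8 smooth muscle genes, and their median of 0.26 lies against it. Skeletal muscle tissue in the RNA of the DEF/CT pool was tested on 15 further muscle genes that had not been looked at, and a median at or below -1 had been set in advance for it and one above -0.5 against it. The median was -0.89, below all random lists but between these bounds, so the explanation may hold and stays open. Tpm2, at 0.39 and named after its values were seen, was counted both among these 15 genes and among the 8 smooth muscle genes. Of the muscle genes Fabp3, Cryab and Des, the last named outside the rule, also belong to other lists. No biological explanation was tested, and with the RNA of several mice in 1 pool the number of mice behind the signal cannot be found.

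Peroxisomal and omega oxidation genes were higher in the DEF/FOS pool by a median of 0.67. Signal-dependent scaling of the arrays is argued against by the median of 0.66 after the loess correction, at percentile 100. Less liver RNA in the DEF/CT pool was tested with the hepatocyte markers, whose median was -0.028 with a median absolute deviation of 0.02. The scaling and centring of the arrays largely remove a loss common to all liver genes, so this value cannot show whether one occurred. It shows only that the peroxisomal genes stand apart from these markers, which a loss common to both would not give. A more fasted state of the DEF/FOS pool stays open, since the fasting list of 14 genes went both ways, with a median of -0.088, an SD of 0.37 and 5 members above 0, Gadd45a 1.61-fold, Igfbp1 1.43-fold and Lpin1 1.39-fold higher and Cited2 1.46-fold lower, while ketone body synthesis had a median of 0.40 and Pdk4 was 1.52-fold higher. The fibre and the diet oil, which may each act on these genes, stay open and untested, since the pools differ in both.

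Cell cycle genes were higher in the DEF/FOS pool by a median of 0.99, mostly at low signal. If noise of dim probe sets were the cause, the members above the 75th percentile of signal should lie inside random lists, and the median of these 5 members was 0.14 at percentile 82.9, as noise would give, but 2 of them, Ccnd1 at 1.79 and Rrm2 at 0.96, a gene named after its values were seen, lay far above the SDs of 0.23 and 0.32 of genes of like signal. The 16 dimmer members, 15 of them above 0, had a median of 1.00 at percentile 100 of equally dim random lists, a value that independent noise would seldom give, so noise shared between probe sets or a true difference of genes at low level remains possible. Dividing immune cells in the DEF/FOS pool were tested with 4 immune marker lists, whose medians ran from -0.46 in B and plasma cells to 1.06 in neutrophils, and these do not settle it. The cell cycle difference is therefore open.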
